A study of Mus musculus with 12 samples.

How the data were processed

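RNA was measured by bulk sequencing in 12 libraries of mouse epiblast stem cells grown as embryoid bodies. The cells carried a FLAG-tagged Mixl1 transgene under doxycycline control, per the labels. The labels give 4 groups of 3 libraries. NoDox_d2 and NoDox_d4 were collected without doxycycline on days 2 and 4. D1Dox_d2 and D3Dox_d4 received doxycycline at 1 µg/mL and were collected on days 2 and 4. The labels do not define the number after the D in a group name. No cells without the transgene were given doxycycline, so an effect of the drug and one of Mixl1 cannot be separated here.

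Per the labels' protocols, libraries were made with the NEBNext Ultra II kit, sequenced as 150 bp paired reads and trimmed with Trim Galore to a minimum length of 50 bp. The submitters' processing notes name STAR, featureCounts, DESeq2 and the builds GRCm38 and mm10. Per the file headers, the deposited values are raw counts of read pairs per gene, made with featureCounts 2.0.1, the GENCODE vM25 annotation and no strand setting. Reads from a gene and from an antisense partner were therefore counted alike. Of 156 genes taken for the text, 11 share more than 10% of their exon bases with a gene on the opposite strand: Smarcd3, Hoxa3, Ccna2, Shh, Gbx2, Spry1, Hoxaas2, Bnip3, Clca4a, Pou5f1 and Hoxb3. Gbp2, Gbp2b, Cyp2b23 and Clca4a belong to families of close copies. Their counts are uncertain for another reason, as reads can match several copies, which was not tested. A gene count also cannot tell the Mixl1 transgene from the endogenous gene. Gene symbols were matched by Ensembl identifier for 55141 of 55487 genes.

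Libraries held 24100487 to 28020036 counts, so that 3 counts correspond to 0.106 to 0.130 CPM, the library-scaled counts of edgeR. Intervals of ratios cover counting error only.

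Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). TMM normalization, the filterByExpr filter and one coefficient per group were used. All 12 libraries entered the fit, with 8 residual degrees of freedom. Of the genes counted, 18109 were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each log2 fold change is given ± a standard error (SE), and group values are mean CPM. The SE was derived as the size of the log2 fold change divided by the square root of the F statistic. Where a group holds few counts, as for Vip at day 2 and Dbh at day 4 without doxycycline, it can understate the counting error. The 4 comparisons were D1Dox_d2 against NoDox_d2, D3Dox_d4 against NoDox_d4, the difference of these effects (day 4 minus day 2), and NoDox_d4 against NoDox_d2. Mixl1 was also compared with an exact permutation test of CPM, two-sided, whose smallest p for 3 against 3 is 0.1.

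A set of 27 gene lists with 365 genes, written from textbook knowledge, was tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The lists cover core pluripotency, primed epiblast, primitive streak, definitive endoderm, visceral and yolk sac endoderm, node and notochord, nascent and paraxial mesoderm, lateral plate and cardiac mesoderm, blood and endothelium, neural ectoderm, surface ectoderm, trophoblast, germ cell, mesenchymal and EMT, epithelial, the Nodal, Wnt, BMP and FGF pathways, posterior Hox and Cdx, proliferation, p53 response, ATF4 stress response, mitochondrially encoded genes, glycolysis and hypoxia, fibroblast feeder, and immediate early and heat shock genes. Counts of called members are given over all genes tested and adjusted over the list alone.

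The lists, the tests, the comparisons and the rule for named genes were set before the data were examined. The rule took Mixl1, the 6 highest and the 6 lowest called log2 fold changes with a mean of at least 5 CPM in the higher group, no overlap between libraries of the groups and a gene symbol that is no predicted-gene name, and called list members. It took up to 4 members with the lowest adjusted p from lists with at least 3 calls and up to 2 from the others. To keep the text short, this was later reduced to the 2 lowest adjusted p per list, plus a list's only called member in a direction and all called members of lists with fewer than 3 calls. That reduction was set after values had been seen, and not all genes it took are named. It added 3 genes outside the rule, Etv2, Id2 and Spry4 at day 2. Of the genes the rule took, 1 at day 2 and 1 for the difference are not reported, with none in their place. Asns, T, Xist and the Y-linked genes were also chosen after their values were seen. Only Y-linked genes near the start of the chromosome were summed.

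The alternatives tried were DESeq2 size factors, upper-quartile scaling, no filter, a stricter filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 test, the replicate number as a block, only the libraries compared, a minimum fold of 1.5, an adjusted p under 0.01, removal of mitochondrial genes, robust moderation, camera with an estimated correlation, fry, and each library left out in turn. A fit without both NoDox libraries numbered 1, one without those numbered 2 and 3 for the counts of genes, and a block over the 6 NoDox libraries alone, were added after the data were seen. Same-numbered NoDox libraries of the 2 days deviated together from their group means, with correlations of 0.545, 0.361 and 0.308, so the numbers were read as pairs for that comparison. This pairing comes from the values, as the labels name no shared batch, and replicate 2 of day 2 correlated best with replicate 3 of day 4, at 0.416, as did replicate 3 of day 2 with replicate 2 of day 4, at 0.325.

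On simulated counts with known changes, the day 2 comparison (17662 genes) recovered 44.8% of 2-fold and 83.8% of 4-fold changes, with 8 of 134 calls false. Day 4 (17641 genes) recovered 53.1% and 86.6%, with 4 of 139 false. The difference of the effects (17638 genes) recovered 21.6% and 75.8%, with 8 of 104 false. Time without doxycycline (17643 genes) recovered 45.8% and 81.4%, with 13 of 136 false. In the day 2 simulation, 1 unchanged list was also called. Unchanged genes were drawn around a single mean over all libraries, with a spread set by expression level. The simulated libraries thus held no NoDox replicate that stood apart and no unequal spread between groups. These rates may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.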

Results

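The series measured gene expression in embryoid bodies made from mouse epiblast stem cells, a primed pluripotent cell type, in which doxycycline induces Mixl1, a homeobox gene of the primitive streak. The question is how the time of Mixl1 induction changes the cells' expression. There were 12 libraries in 4 groups of 3, with 24100487 to 28020036 counts and 24156 to 27347 genes with at least 1 count each. Mitochondrially encoded genes took 2.76% to 5.21% of the counts. A single clone-named gene took 2.63%, 4.15% and 8.61% in D1Dox_d2 and 1.44% to 2.12% in the other libraries. D1Dox_d2 libraries also held the most genes with a count, 26556 to 27347 against at most 25872 elsewhere. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, whether biological or technical.

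Libraries of D1Dox_d2 lay apart from all others on the first principal component, at 75.6 to 80.1 against −55.7 to 20.3, and those of D3Dox_d4 on the second, at 63.1 to 66.6. Replicates correlated at 0.989 to 0.991 in D1Dox_d2 and 0.987 to 0.992 in D3Dox_d4 (Pearson across genes of log2 CPM). In both NoDox groups replicate 1 stood apart. It correlated at 0.957 and 0.961 with the others in NoDox_d2, which correlated at 0.991, and at 0.960 and 0.961 in NoDox_d4, against 0.990.

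**Figure D1:**
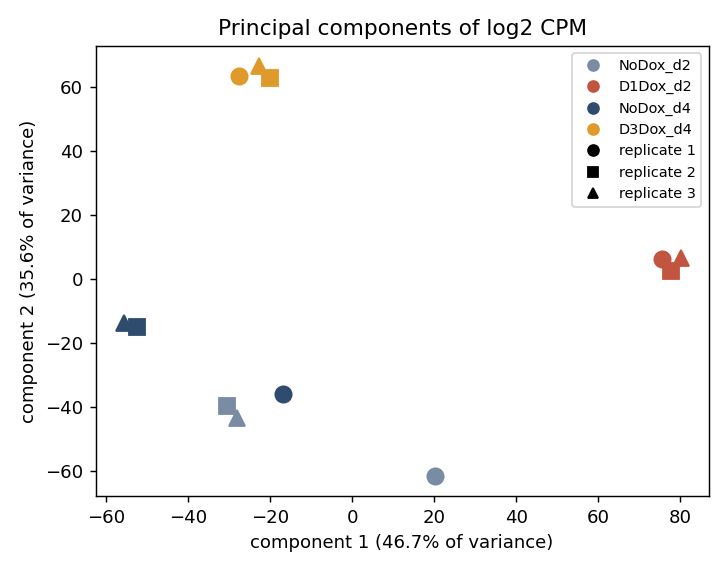
Each point is a library, placed by the first 2 principal components of log2 CPM over the 2000 most variable genes, which carry 46.7% and 35.6% of the variance; colour gives the group and shape the replicate. D1Dox_d2 lies at 75.6 to 80.1 on the first component and D3Dox_d4 at 63.1 to 66.6 on the second, and replicate 1 of each NoDox group lies away from replicates 2 and 3.

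Mixl1 (ENSMUSG00000026497.7, chromosome 1, 180693043 to 180697034, minus strand, GRCm38) was high in every doxycycline library. Its mean was 380 ± 16.2 CPM (SD, n = 3) in D1Dox_d2 and 448 ± 30.2 (SD, n = 3) in D3Dox_d4, against 1.52 ± 0.367 (SD, n = 3) in NoDox_d4. In NoDox_d2 it was 0.593 and 1.15 CPM in replicates 2 and 3. The library labelled NoDox_d2 replicate 1 held 91.0 CPM, 23.9% of the D1Dox_d2 mean, although its label gives no doxycycline. The count does not tell whether this was the transgene or endogenous Mixl1. Mixl1 rose at day 4 by a log2 fold change of 8.20 ± 1.57 (SE, edgeR adjusted p = 0.00311).

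At day 2 the Mixl1 log2 fold change was 3.62 ± 1.22 (adjusted p = 0.0453), and 8.74 without NoDox_d2 replicate 1. The day 2 call was lost without D1Dox_d2 replicate 1 (adjusted p = 0.0845), 2 (0.0858) or 3 (0.0933), and without NoDox_d2 replicate 2 (0.0686) or 3 (0.0874). It was also lost with only the libraries compared in the fit (0.1203) and with robust moderation (0.0507). The exact permutation p was 0.1 on both days, the smallest that 3 against 3 allows. D3Dox_d4 and D1Dox_d2 differed by 0.24 ± 1.10 (edgeR adjusted p = 0.875), in a fit whose spread for Mixl1 includes NoDox_d2 replicate 1. Their libraries did not overlap, at 417 to 478 against 362 to 392 CPM (exact permutation p = 0.1). The difference of the effects was 4.58 ± 1.77 (adjusted p = 0.107), or −0.53 without NoDox_d2 replicate 1, and it was called without NoDox_d2 replicate 2 (0.0451). Between NoDox_d4 and NoDox_d2 it was −4.35 ± 1.40 (adjusted p = 0.0703, exact p = 0.9), or 0.77 without NoDox_d2 replicate 1, with a call without NoDox_d2 replicate 2 (0.0192) or 3 (0.0303). With no filter on low counts both were called, at adjusted p 0.0212 and 0.00553.

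**Figure D2:**
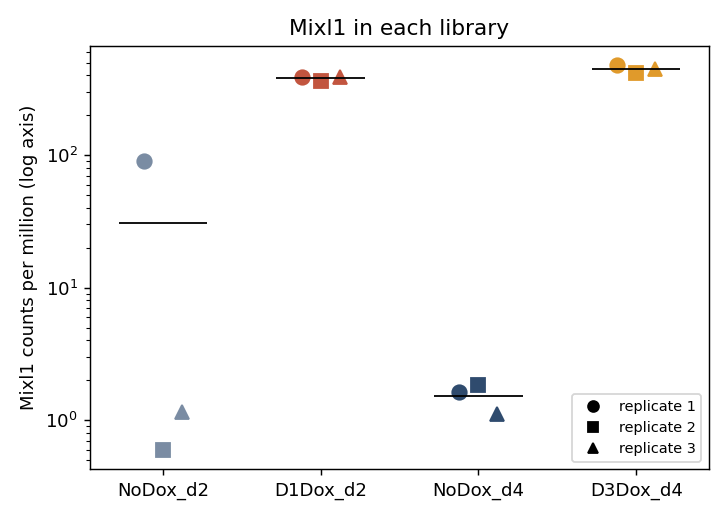
Mixl1 in CPM on a log axis for each library by group; shapes give the replicate and lines the group means. Doxycycline libraries lie between 362 and 478 CPM, and the library labelled NoDox_d2 replicate 1 lies at 91.0, above the other NoDox libraries.

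At day 2, doxycycline raised Vip, which encodes a neuropeptide, from 0.159 to 107 CPM (log2 fold change 9.33 ± 0.25, n = 3 per group). Nanog, a pluripotency factor, fell (−2.57 ± 0.31), as did Sox3 (−3.03 ± 0.17), an epiblast and neural factor. The anterior streak and endoderm genes Gsc (4.43 ± 0.45) and Cer1 (5.99 ± 0.58) rose, while Meox1 (−4.46 ± 0.71), a somite homeobox gene, fell.

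Of 18109 genes, 2705 rose and 2431 fell, 5136 in all. Among the largest rises were genes with 1 to 3 counts over the NoDox_d2 libraries, given as count ratios with a 95% interval. These were 626 (112 to 24775) for the serotonin receptor gene Htr3b, 513 (91.6 to 20309) for the anion transporter gene Slc26a7, 398 (110 to 3292) for Dmbt1 and 240 (81.7 to 1166) for Chodl. The largest falls, besides Meox1, were in Zic1 (−4.69 ± 0.75), a neural zinc finger gene, the retinoic acid-degrading enzyme genes Cyp26b1 (−4.60 ± 1.03, or −4.01 without NoDox_d2 replicate 2) and Cyp26c1 (−4.47 ± 0.72), the bHLH repressor gene Hes3 (−4.51 ± 0.40) and Pde11a (−4.35 ± 0.74).

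Of 12 primed epiblast genes, 7 fell, among them Sox3 and the DNA methyltransferase gene Dnmt3b (−1.71 ± 0.13), and 5 did not pass; adjusted over the list alone, 8 fell and 1 rose. The list fell by camera (adjusted p = 0.000115; adjusted p = 0.284 with an estimated correlation). Of 12 core pluripotency genes, 2 rose, among them the naive-state factor Esrrb (4.60 ± 0.18), 2 fell, among them Nanog, and 8 did not pass (3 and 4 adjusted over the list alone). That list did not pass (adjusted p = 0.396), and its median lay below 0 while its mean lay above. Of 8 germ cell genes, 5 fell, among them Ifitm3 (−0.87 ± 0.11) and the receptor gene Kit (−1.10 ± 0.19), and 3 did not pass (5 fell adjusted over the list alone). The germ cell list fell (adjusted p = 0.00933; adjusted p = 0.284 with an estimated correlation), but not without NoDox_d2 replicate 1 (0.0528) or both NoDox libraries numbered 1 (0.0682).

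Of 14 primitive streak genes, 6 fell, among them Wnt8a (−3.22 ± 0.15), 2 rose, among them Gsc, and 6 did not pass (7 and 2 adjusted over the list alone). The list did not pass (adjusted p = 0.159) but fell without NoDox_d2 replicate 2 (0.00590) or 3 (0.0394). Without both NoDox libraries numbered 1, 7 of its genes rose and 6 fell, and camera pointed upward without a call (adjusted p = 0.472). T, the brachyury gene of the streak, stood at 1261 CPM in NoDox_d2 replicate 1 against 100 and 142 in replicates 2 and 3. Of 15 definitive endoderm genes, 3 rose, among them Gsc and Cer1, 2 fell and 10 did not pass (3 and 3 adjusted over the list alone; list adjusted p = 0.319). Of 11 node and notochord genes, 2 rose, the Wnt inhibitor gene Dkk1 (4.97 ± 0.19) and the Nodal inhibitor gene Lefty1 (2.00 ± 0.46), 2 fell and 7 did not pass (2 and 2 adjusted over the list alone; list adjusted p = 0.2499). None of 8 visceral and yolk sac endoderm genes passed in edgeR, over all genes or over the list alone (1 at an unadjusted p under 0.05, 0 in DESeq2; list adjusted p = 0.925). Median, mean and camera direction differed in sign for the node list and both endoderm lists.

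Of 15 nascent and paraxial mesoderm genes, 11 fell, over all genes and adjusted over the list alone, among them Meox1, the Notch ligand gene Dll1 (−1.79 ± 0.22) and Tcf15 (−2.31 ± 0.33), and 4 did not pass. That list fell (adjusted p = 0.000115; adjusted p = 0.284 with an estimated correlation). Of 14 posterior Hox and Cdx genes, 7 fell, among them Hoxb1 (−1.79 ± 0.13) and Hoxa3 (−1.42 ± 0.18), and 7 did not pass (10 fell adjusted over the list alone). This list also fell (adjusted p = 9.83e-06; adjusted p = 0.284 with an estimated correlation). Of 11 lateral plate and cardiac genes, 2 rose, Tbx20 (5.17 ± 0.42, or 5.97 without NoDox_d2 replicate 1), a cardiac T-box gene, and Smarcd3 (0.74 ± 0.15), and 9 did not pass (2 rose adjusted over the list alone). Their list did not pass (adjusted p = 0.105) but rose without NoDox_d2 replicate 1 (0.00423).

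Of 13 blood and endothelium genes, 6 rose, among them Gata2 (4.06 ± 0.40), a blood progenitor factor, and the endothelial adhesion gene Esam (2.96 ± 0.35). The 1 that fell was Etv2 (−1.23 ± 0.34), a factor of early endothelium chosen after its values were seen, whose call was lost without D1Dox_d2 replicate 2 or 3 or NoDox_d2 replicate 2 or 3 (adjusted p 0.0503 to 0.0842) or with only the libraries compared (0.0584). The other 6 did not pass, and counts adjusted over the list alone were 6 and 1. The list rose (adjusted p = 0.00558; adjusted p = 0.574 with an estimated correlation), in libraries with Y-linked sums of 4.19 to 5.42 CPM against at most 1.06 elsewhere. Of 12 mesenchymal and EMT genes, 6 rose, over all genes and adjusted over the list alone, among them the cadherin gene Cdh11 (1.17 ± 0.32) and Snai2 (1.74 ± 0.48), and 6 did not pass. Cdh11 was lost without D1Dox_d2 replicate 3 (0.0642), NoDox_d2 replicate 2 (0.0720) or 3 (0.0747), and Snai2 without D1Dox_d2 replicate 2 (0.0649) or NoDox_d2 replicate 3 (0.0744). The mesenchymal list did not pass (adjusted p = 0.111) but rose without NoDox_d2 replicate 1 (0.0181). In the same D1Dox_d2 libraries, 9 of 13 fibroblast feeder genes also rose.

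Of 16 neural ectoderm genes, 7 fell, among them Zic1 and Pax3 (−3.65 ± 0.51), 3 rose, among them the proneural gene Neurog2 (2.46 ± 0.34), and 6 did not pass (8 and 3 adjusted over the list alone). The list did not pass (adjusted p = 0.159) but fell without NoDox_d2 replicate 1 (0.00503). Of 11 surface ectoderm genes, 4 rose, among them Gata3 (3.24 ± 0.28), and 1 fell, Grhl2 (−2.00 ± 0.26), an epithelial factor, while 6 did not pass (5 and 1 adjusted over the list alone; list adjusted p = 0.168). Of 7 trophoblast genes, Gata3 rose, 2 fell, among them Cdx2 (−3.60 ± 0.88, or −1.98 without NoDox_d2 replicate 1), and 4 did not pass (1 and 2 adjusted over the list alone; list adjusted p = 0.640). Of 12 epithelial genes, 2 rose, among them the keratin gene Krt18 (1.51 ± 0.28), 1 fell, the E-cadherin gene Cdh1 (−1.14 ± 0.24), and 9 did not pass (2 and 1 adjusted over the list alone; list adjusted p = 0.807). Median, mean and camera direction of the trophoblast list differed in sign.

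**Figure D3:**
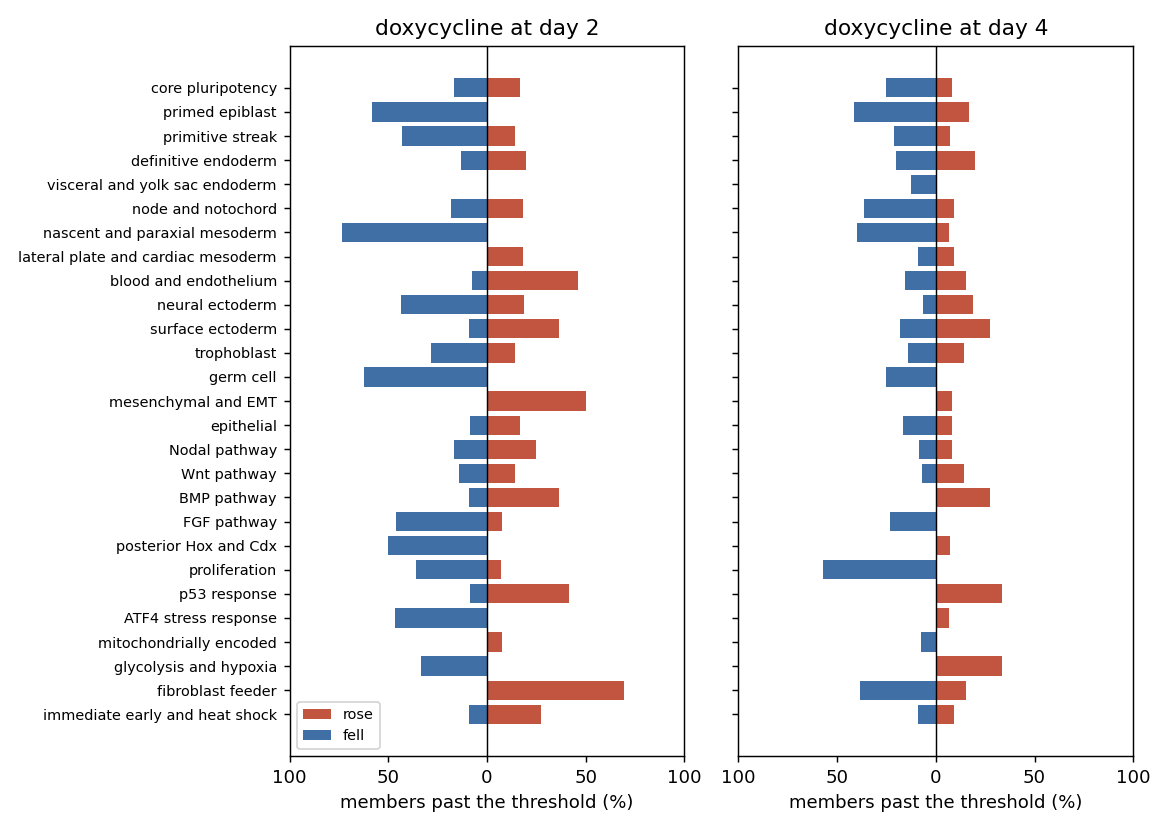
For each of the 27 lists, bars give the percent of tested members that rose (right) or fell (left) past an adjusted p of 0.05 under doxycycline at day 2 (left panel) and day 4 (right panel). At day 2, 9 of 13 fibroblast feeder genes rose and 11 of 15 nascent and paraxial mesoderm genes fell; at day 4, 8 of 14 proliferation genes fell.

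Of 13 fibroblast feeder genes, 9 rose at day 2, among them the collagen gene Col1a2 (3.34 ± 0.13) and the matrix gene Postn (3.36 ± 0.29), and 4 did not pass (10 rose adjusted over the list alone). This list rose (adjusted p = 6.81e-09; adjusted p = 0.284 with an estimated correlation). Xist and the summed Y-linked genes were also highest in these libraries. Y-linked genes near the start of the chromosome (7 with counts) summed to 5.00, 4.19 and 5.42 CPM in D1Dox_d2 and at most 1.06 in the other libraries. Xist, expressed from the inactive X chromosome, stood at 12.1 to 19.7 CPM in D1Dox_d2 and at most 2.01 elsewhere. Of 15 ATF4 stress response genes, 7 fell, among them Ddit4 (−2.01 ± 0.42) and the serine synthesis gene Phgdh (−1.54 ± 0.42), and 8 did not pass (9 fell adjusted over the list alone). The ATF4 list fell (adjusted p = 0.0196; adjusted p = 0.695 with an estimated correlation), but not without NoDox_d2 replicate 3 (0.0640) or in fry (0.191). Phgdh lost its call without D1Dox_d2 replicate 2 (0.0626) or 3 (0.0671) or NoDox_d2 replicate 2 (0.0641) or 3 (0.0742). Asns, a target of ATF4, stood at 72.7 to 80.7 CPM in D1Dox_d2, 97.0 in NoDox_d2 replicate 1, and 628 and 710 in replicates 2 and 3.

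**Figure D4:**
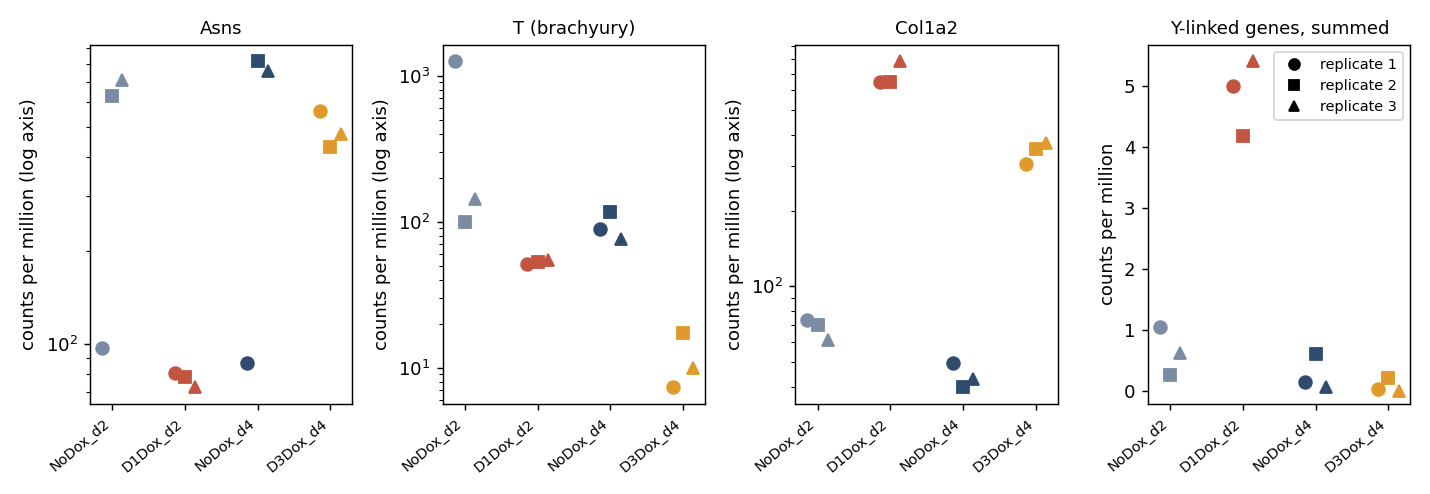
Asns, T and Col1a2 (log axes) and the sum of 7 Y-linked genes (linear axis) in CPM for each library by group; shapes give the replicate. Asns is at 97.0 and 87.2 CPM in replicate 1 of the NoDox groups and at least 628 in their replicates 2 and 3, and the Y-linked sum is at least 4.19 only in the 3 D1Dox_d2 libraries.

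In 8330 genes (46.0%) the groups of day 2 did not overlap, against 10% by chance. The count of 5136 fell to 3371 without D1Dox_d2 replicate 2, 3048 without D1Dox_d2 replicate 3, 3334 without NoDox_d2 replicate 2 and 3142 without NoDox_d2 replicate 3, and was 9902 without both NoDox libraries numbered 1. That last fit also called neural ectoderm (1.11e-06), mesenchymal (2.81e-05), lateral plate (0.00109) and definitive endoderm (0.0119), and fry called the last 3 (0.0353, 0.0472 and 0.0353) and surface ectoderm (0.00481).

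At day 4, doxycycline raised Dbh, an enzyme gene of noradrenaline synthesis, from 0.118 to 134 CPM (log2 fold change 10.09 ± 0.21, n = 3 per group), and Cdh12 (8.62 ± 0.40), a cadherin gene. Shh, the Hedgehog ligand gene of node and notochord, fell (−5.70 ± 0.60), as did its target Gli1 (−3.47 ± 0.40). The replication gene Mcm5 also fell (−0.95 ± 0.11).

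Of 18109 genes, 2424 rose and 1839 fell, 4263 in all (2185 and 2227 with upper-quartile scaling). Vip had 1 count over the NoDox_d4 libraries and a count ratio of 9880 (1773 to 390295). That ratio was 1521 (421 to 12563) for Tlx2, a homeobox gene of peripheral neurons, and 995 (178 to 39356) for Otp, a hypothalamic homeobox gene. The neuronal gap junction gene Gjd2 rose by 8.76 ± 0.57, or 10.26 without NoDox_d4 replicate 3. Falls were also large in Samd3 (−4.68 ± 0.79), Igfbp5 (−3.74 ± 0.47), the fatty acid receptor gene Cd36 (−3.46 ± 0.87) and Foxd1 (−3.42 ± 0.79, or −2.07 without NoDox_d4 replicate 1). Cd36 was −2.84 without NoDox_d4 replicate 1 and lost its call without D3Dox_d4 replicate 1 (adjusted p = 0.0548) or 2 (0.0525).

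Of 12 core pluripotency genes, 3 fell, among them Nanog (−1.66 ± 0.31), 1 rose, Esrrb (1.46 ± 0.16), and 8 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.426). Of 12 primed epiblast genes, 5 fell, among them Sox3 (−2.12 ± 0.17) and Dnmt3b (−0.97 ± 0.13), 2 rose and 5 did not pass (8 and 2 adjusted over the list alone). The list did not pass (adjusted p = 0.266) but fell without NoDox_d4 replicate 1 (0.00268). Of 8 germ cell genes, 2 fell, Kit (−0.99 ± 0.19) and Ifitm3 (−0.52 ± 0.11), and 6 did not pass, likewise adjusted over the list alone (list adjusted p = 0.412). Of 14 primitive streak genes, 3 fell, among them Wnt8a (−2.14 ± 0.14), 1 rose, Gsc (4.69 ± 0.47, or 5.602 without NoDox_d4 replicate 2), and 10 did not pass, likewise adjusted over the list alone (list adjusted p = 0.385). Of 15 definitive endoderm genes, 3 rose, among them Gsc, 3 fell, among them the claudin gene Cldn6 (−1.90 ± 0.33), and 9 did not pass (3 and 4 adjusted over the list alone; list adjusted p = 0.657). Dab2 (−1.15 ± 0.25) fell alone of 8 visceral and yolk sac endoderm genes, 7 of which did not pass, likewise adjusted over the list alone (list adjusted p = 0.402).

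Of 11 node and notochord genes, 4 fell, among them Shh, 1 rose, Dkk1 (1.91 ± 0.17), and 6 did not pass, likewise adjusted over the list alone (list adjusted p = 0.402). Of 15 nascent and paraxial mesoderm genes, 6 fell, among them Foxc2 (−2.25 ± 0.49, or −1.20 without NoDox_d4 replicate 1), 1 rose, Cited2 (0.44 ± 0.07), and 8 did not pass (6 and 2 adjusted over the list alone; list adjusted p = 0.402). Of 11 lateral plate and cardiac genes, Tbx20 rose (5.07 ± 0.44), Mef2c fell (−1.41 ± 0.23) and 9 did not pass, likewise adjusted over the list alone (list adjusted p = 0.829). Of 13 blood and endothelium genes, 2 rose, Gata2 (2.84 ± 0.38) and the endothelial gene Pecam1 (1.73 ± 0.42, or 2.41 without NoDox_d4 replicate 1), 2 fell and 9 did not pass, likewise adjusted over the list alone (list adjusted p = 0.842). Of 14 posterior Hox and Cdx genes, 1 rose, Hoxa3 (0.65 ± 0.17, adjusted p = 0.0752 without D3Dox_d4 replicate 3), and 13 did not pass, likewise adjusted over the list alone (list adjusted p = 0.651).

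Of 16 neural ectoderm genes, 3 rose, among them Gbx2 (2.10 ± 0.22), a hindbrain homeobox gene, and Neurog2 (3.01 ± 0.33), 1 fell, Olig3 (−3.15 ± 0.59), and 12 did not pass, likewise adjusted over the list alone (list adjusted p = 0.651). Of 11 surface ectoderm genes, 3 rose, among them the epidermal factor gene Trp63 (2.63 ± 0.41), 2 fell, among them Wnt4 (−1.64 ± 0.22), and 6 did not pass, likewise adjusted over the list alone (list adjusted p = 0.914). Of 7 trophoblast genes, Gata3 rose (0.83 ± 0.27), Krt7 fell (−1.22 ± 0.35) and 5 did not pass, likewise adjusted over the list alone (list adjusted p = 0.792). Calls of Gata3 (adjusted p 0.123 to 0.150 without D3Dox_d4 replicate 1 or 3 or NoDox_d4 replicate 2 or 3, 0.0515 with DESeq2 size factors, 0.0566 with upper-quartile scaling, 0.0510 with the stricter filter and 0.12003 with only the libraries compared) and Krt7 (0.0560 to 0.0879 without any D3Dox_d4 replicate or NoDox_d4 replicate 2 or 3) were lost. Of 12 epithelial genes, 1 rose, Cldn3 (1.74 ± 0.27), 2 fell, among them Cdh1 (−1.51 ± 0.25), and 9 did not pass, likewise adjusted over the list alone (list adjusted p = 0.651). Of 12 mesenchymal genes, Mmp2 rose (0.72 ± 0.17, adjusted p = 0.0596 with only the libraries compared) and 11 did not pass, likewise adjusted over the list alone (list adjusted p = 0.935).

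Of 14 proliferation genes, 8 fell, among them the replication helicase genes Mcm5 and Mcm2 (−0.58 ± 0.08), and 6 did not pass (11 fell adjusted over the list alone). This was the 1 list of 27 to pass at day 4 (adjusted p = 1.13e-05; adjusted p = 0.811 with an estimated correlation). Of 13 fibroblast feeder genes, 2 rose, among them Col1a2 (2.96 ± 0.13), 5 fell, among them the smooth muscle actin gene Acta2 (−2.66 ± 0.57, or −1.28 without NoDox_d4 replicate 1), and 6 did not pass, likewise adjusted over the list alone (list adjusted p = 0.657). Y-linked genes summed to at most 0.221 CPM in D3Dox_d4. Of 15 ATF4 stress response genes, 1 rose, Gdf15 (2.60 ± 0.65, or 3.28 without NoDox_d4 replicate 2), and 14 did not pass, likewise adjusted over the list alone (list adjusted p = 0.651). Asns stood at 431 to 564 CPM in D3Dox_d4, 87.2 in NoDox_d4 replicate 1, and 816 and 756 in replicates 2 and 3. Median, mean and camera direction differed in sign for the neural, mesenchymal, ATF4, fibroblast and Wnt lists of day 4.

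In 7361 genes (40.6%) the groups of day 4 did not overlap, against 10% by chance. The count of 4263 was 2756 without D3Dox_d4 replicate 3 and 7168 without both NoDox libraries numbered 1, and 7445 without those numbered 2 and 3. The fit without both numbered 1 also called primed epiblast (3.32e-07), node (0.0126) and paraxial mesoderm (0.0150).

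Many genes moved alike on both days, although the comparisons share no library. Of 1868 genes called on both, 1648 (88.2%) had one direction, among them Vip, Gsc, Tbx20, Gata2 and Col1a2 upward and Nanog, Sox3 and Wnt8a downward. Col1a2 rose at day 2 in libraries with high Y-linked sums and at day 4 in libraries without them, so its rises need not share a source. Upward, 1042 were shared against 362 for independent lists, downward 606 against 247, and 220 moved oppositely against 600. Independent lists leave out that same-numbered NoDox libraries of the days deviated together (correlations 0.545, 0.361 and 0.308). By itself this adds 0.0289 (12.02%) to the covariance of 0.241 between the effects, taken as differences of mean log2 CPM. Across all tested genes the log2 fold changes correlated at 0.400 (Pearson) and 0.2396 (Spearman), although genes are not independent replicates. The shared count of 1648 was 1098 without D1Dox_d2 replicate 3 and 3813 without both NoDox libraries numbered 1. Of these 1648 genes, 196 were also called for the difference of the effects.

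**Figure D5:**
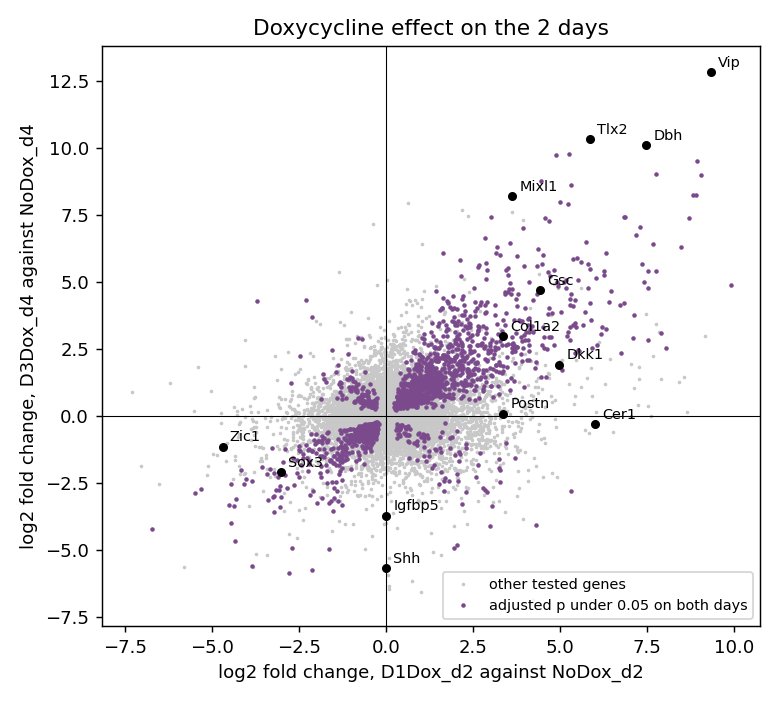
Fitted log2 fold changes of each tested gene under doxycycline at day 2 (x axis) and day 4 (y axis); purple points passed an adjusted p of 0.05 on both days, and named genes are black. Vip lies high on both axes, Cer1 (5.99) and Postn (3.36) mainly on the day 2 axis, and Shh (−5.70) and Igfbp5 (−3.74) on the day 4 axis; fitted values of Vip and Tlx2 at day 4 rest on 1 and 2 NoDox counts.

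The effect of doxycycline differed between the days in 2336 genes, 1206 with a higher and 1130 with a lower effect at day 4 (1067 and 1238 with upper-quartile scaling). Among genes induced more at day 4 were Thsd7b (difference 5.36 ± 0.88) and the galanin gene Gal (5.14 ± 0.97). Induced more at day 2, the secreted inhibitor gene Cer1 (−6.29 ± 0.73) stood at 83.2 CPM in D1Dox_d2 and 4.08 in D3Dox_d4, and the ephrin receptor gene Epha3 (−6.23 ± 0.65) at 41.7 and 6.57. Both differences exceed the change between the doxycycline groups, so part of each lies in a change between the NoDox groups. Gal was 4.01 without NoDox_d2 replicate 1 and 6.11 without NoDox_d4 replicate 2.

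Higher effects at day 4 were also large in Hoxaas2 (4.47 ± 0.68), a transcript of the HoxA cluster, and Ecel1 (4.58 ± 1.05), a peptidase gene of neurons. Ecel1 was 5.18 without NoDox_d4 replicate 2 and lost its call without D1Dox_d2 replicate 2 or 3 (adjusted p 0.0507 and 0.0513). Lower effects were large in the growth factor gene Igf1 (−6.41 ± 1.44) and the collagen gene Col14a1 (−6.27 ± 1.52). Their day 2 effects were measured in D1Dox_d2 libraries, with Y-linked sums of 4.19 to 5.42 CPM against at most 1.06 elsewhere. A source other than the induced cells therefore stays open for both genes. Without NoDox_d4 replicate 1, Igf1 was −3.58 and Col14a1 −3.09, and without NoDox_d2 replicate 1 they were −7.26 and −6.95. Col14a1 lost its call without D1Dox_d2 replicate 3, D3Dox_d4 replicate 2 or 3, or NoDox_d2 replicate 2 or 3 (adjusted p 0.0504 to 0.0588). Tlx2, Dmbt1 and Slc26a7, with 3 or fewer counts in a NoDox group, stood at 29.2, 10.02 and 6.43 CPM in D1Dox_d2 and at 40.1, 0.104 and 0.331 in D3Dox_d4.

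Of 27 lists, 13 passed for the difference of the effects. Higher at day 4 were posterior Hox and Cdx (adjusted p = 0.000228; 3 of 14 members higher, 4 adjusted over the list alone), with Hoxb1 (1.75 ± 0.18) and Hoxa3 (2.07 ± 0.25), and nascent and paraxial mesoderm (0.00459; 3 of 15, 5 over the list alone), with Dll1 (2.09 ± 0.30). Their adjusted p = 0.415 with an estimated correlation, and the mesoderm list was lost without NoDox_d2 replicate 1 (0.0723). Neural ectoderm (0.0191; 4 of 16, 5 over the list alone), with En1 (1.68 ± 0.31) and Gbx2 (1.37 ± 0.31), and primed epiblast (0.0457; 4 of 12 higher and 1 lower, 5 and 1 over the list alone), with Pou3f1 (1.99 ± 0.31), were also higher; their adjusted p = 0.425 with an estimated correlation. Primed epiblast was lost without D3Dox_d4 replicate 2 (0.0603), NoDox_d2 replicate 2 (0.0507) or 3 (0.0587), NoDox_d4 replicate 1 (0.171) or both NoDox libraries numbered 1 (0.0911), and with the stricter filter (0.0633). ATF4 stress response (0.00186; 1 of 15, likewise over the list alone), with Ddit4 (2.52 ± 0.58, lost without D1Dox_d2 replicate 3 at 0.0510), and glycolysis and hypoxia (0.0297; 4 of 15, 5 over the list alone), with Bnip3 (1.43 ± 0.34, lost without D1Dox_d2 replicate 2 at 0.0525), followed. Their adjusted p = 0.486 and 0.426 with an estimated correlation, and glycolysis was lost without D3Dox_d4 replicate 2 (0.102) or NoDox_d4 replicate 3 (0.0570). The NoDox controls were uneven for the ATF4 target Asns, at 97.0 and 87.2 CPM in replicate 1 of NoDox_d2 and NoDox_d4. In their replicates 2 and 3 it stood at 628 CPM or more.

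Lower at day 4 were fibroblast feeder (adjusted p = 1.41e-07; 8 of 13 members lower, likewise over the list alone), with Postn (−3.28 ± 0.40), and blood and endothelium (0.00153; 4 of 13, 5 over the list alone), with Esam (−3.60 ± 0.51). Y-linked sums were 4.19 to 5.42 CPM in D1Dox_d2 and at most 0.221 in D3Dox_d4, and Xist stood at 12.1 to 19.7 and at most 0.627. Also lower were node and notochord (0.00367; 3 of 11, likewise over the list alone), with Shh (−5.69 ± 0.76, or −6.52 without NoDox_d2 replicate 1) and Dkk1 (−3.06 ± 0.24), and proliferation (0.00367; 3 of 14, 5 over the list alone), with Mki67 (−1.40 ± 0.24). The adjusted p = 0.415 with an estimated correlation for these 4 and for core pluripotency (0.0374; 2 of 12, likewise over the list alone), with Esrrb (−3.14 ± 0.23), which was lost without NoDox_d4 replicate 1 (0.139) or both NoDox libraries numbered 1 (0.0969), with the stricter filter (0.0685) and with the replicate block (0.0552). The Nodal pathway (0.0191; 3 of 12, 4 over the list alone), with Inhba (−5.09 ± 0.85), and lateral plate and cardiac mesoderm (0.0353; 2 of 11, likewise over the list alone), with Smarcd3 (−0.999 ± 0.22), had adjusted p = 0.425 and 0.486 with an estimated correlation. Inhba was −5.81 without NoDox_d2 replicate 1 and −4.25 without NoDox_d4 replicate 1. The lateral plate list was lost without NoDox_d2 replicate 2 (0.0508) or 3 (0.0845) or NoDox_d4 replicate 1 (0.155).

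In fry, primed epiblast (0.0806), neural (0.0806), ATF4 (0.153), glycolysis (0.0765), blood (0.0561), core pluripotency (0.0536), Nodal (0.0806) and lateral plate (0.135) were not called for the difference, while surface ectoderm and immediate early (both 0.0403) were. The other 14 lists did not pass for the difference. Leaving out NoDox_d2 replicate 1 brought calls for Wnt (0.0165), definitive endoderm (0.0165), mesenchymal (0.0121), trophoblast (0.0431), immediate early (0.0419) and primitive streak (0.0332, with the direction turned to lower). Leaving out NoDox_d4 replicate 1 brought them for definitive endoderm (0.00572), germ cell (0.0211) and mitochondrially encoded genes (0.000998), and other libraries did for definitive endoderm (0.0488 without D1Dox_d2 replicate 3, 0.0471 without NoDox_d4 replicate 3, and 0.0450 with the stricter filter), germ cell (0.0429 and 0.0452 without NoDox_d2 replicate 2 and 3), mesenchymal (0.0343 and 0.0304 without NoDox_d4 replicate 2 and 3) and mitochondrially encoded genes (0.0420 without D1Dox_d2 replicate 2). The count of 2336 was 1489, 1226 and 1247 without D1Dox_d2 replicates 1, 2 and 3, 1460 and 1325 without D3Dox_d4 replicates 2 and 3, 5037, 1376 and 1338 without NoDox_d2 replicates 1, 2 and 3, 6424 without both NoDox libraries numbered 1, and 4350 without those numbered 2 and 3.

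Between day 2 and day 4 without doxycycline, the pluripotency factor gene Pou5f1 fell from 472 to 108 CPM (log2 fold change −2.12 ± 0.22, n = 3 per group), as did Tdgf1 (−3.10 ± 0.32), the Nodal co-receptor gene, and the epithelial adhesion gene Epcam (−1.93 ± 0.21). The neural factor genes Pou3f3 (4.10 ± 0.48) and Pou3f2 (2.75 ± 0.28) rose, as did Shh (3.06 ± 0.50, or 3.90 without NoDox_d2 replicate 1, and adjusted p = 0.0665 with only the libraries compared).

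In all, 921 genes rose and 1005 fell, 1926 together. Large rises were in Olig2 (4.27 ± 0.68), a neural tube gene, its value 5.24 without NoDox_d2 replicate 3 and 3.46 without NoDox_d4 replicate 1, in Pantr1 (4.14 ± 0.59), Foxc2 (3.86 ± 0.54, or 2.82 without NoDox_d4 replicate 1) and Tenm2 (3.81 ± 0.73). Hoxc10 (5.78 ± 1.47) was 1.53 without NoDox_d4 replicate 1, and its call was lost without that library or any of the 3 NoDox_d2 libraries (adjusted p 0.0544 to 0.0886) and with the replicate block (0.0527). Large falls were in the interferon-induced genes Gbp2b (−3.64 ± 0.47) and Gbp2 (−3.55 ± 0.45, or −2.95 without NoDox_d2 replicate 1), Cyp2b23 (−3.93 ± 0.66, or −5.15 without NoDox_d4 replicate 1), Clca4a (−3.73 ± 0.81), Wnt6 (−3.49 ± 0.79) and the calponin gene Cnn1 (−3.36 ± 0.28). Clca4a was −2.44 and Wnt6 −1.70 without NoDox_d2 replicate 1, and their calls were lost without NoDox_d4 replicate 2 (Clca4a, 0.0530) or 3 (Clca4a, 0.0554, and Wnt6, 0.0734). With only the libraries compared, calls were lost for Olig2 (0.0644), Pantr1 (0.0504), Foxc2 (0.0561), Tenm2 (0.0998), Hoxc10 (0.188), Cyp2b23 (0.0693), Clca4a (0.0914) and Wnt6 (0.144).

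Of 27 lists, 12 passed between the days. Lists that fell were core pluripotency (adjusted p = 2.81e-09; 5 of 12 members fell, 7 adjusted over the list alone), the Nodal pathway (1.13e-07; 4 of 12, 6 over the list alone), with Foxh1 (−1.49 ± 0.11), epithelial (6.50e-07; 6 of 12, 8 over the list alone), with Cdh1 (−1.40 ± 0.24), and p53 response (6.50e-07; 6 of 12, 8 over the list alone), with Trp53inp1 (−1.33 ± 0.15). With an estimated correlation these had adjusted p = 0.121, 0.153, 0.153 and 0.127. Primed epiblast (0.000261; 5 of 12, likewise over the list alone), with Dnmt3b (−1.47 ± 0.13), primitive streak (0.000261; 4 of 14, 5 over the list alone), with Wnt8a (−1.28 ± 0.14), germ cell (0.000283; 3 of 8, likewise over the list alone), with Ifitm3 (−1.27 ± 0.11), and trophoblast (0.00323; 3 of 7, likewise over the list alone), with Eomes (−2.84 ± 0.56, or −1.68 without NoDox_d2 replicate 1), also fell. Their adjusted p = 0.208, 0.386, 0.153 and 0.371 with an estimated correlation, and the streak list was lost without NoDox_d2 replicate 1 (0.0970) or both NoDox libraries numbered 1 (0.0573). In fry the streak (0.105) and trophoblast (0.0753) lists were not called, and with only the libraries compared Cdh1 (0.0714), Eomes (0.112) and Col1a2 (0.0759) were not. The fibroblast feeder list fell (0.0133; 3 of 13, 5 over the list alone; adjusted p = 0.456 with an estimated correlation), with Col1a2 (−0.63 ± 0.12), and was lost without NoDox_d2 replicate 1 (0.0699) or NoDox_d4 replicate 2 (0.139) or 3 (0.0717) and in fry (0.122).

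Lists that rose were neural ectoderm (adjusted p = 0.00133; 4 of 16 rose and 1 fell, 6 and 1 over the list alone) and posterior Hox and Cdx (0.00343; 4 of 14, 7 rose and 1 fell over the list alone), with Hoxb3 (1.503 ± 0.23, adjusted p = 0.0584 with only the libraries compared). Both had adjusted p = 0.342 with an estimated correlation, and were lost without NoDox_d2 replicate 1 (neural, 0.0749) or NoDox_d4 replicate 1 (Hox, 0.104) and in fry (Hox, 0.0635). Mitochondrially encoded genes rose as a list (0.00302; adjusted p = 0.514 with an estimated correlation), but not without NoDox_d4 replicate 2 (0.158) or in fry (0.147). None of its 13 members passed in edgeR, over all genes or over the list alone (6 at an unadjusted p under 0.05, 2 in DESeq2). In NoDox_d4 replicate 2 these genes took 5.21% of the counts.

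The other 15 lists did not pass. Single libraries left out brought calls for node and notochord, paraxial mesoderm, blood, mesenchymal, BMP, FGF, Wnt, ATF4 and immediate early genes. Without NoDox_d2 replicate 1 these were paraxial mesoderm (0.000639), mesenchymal (0.000639), node (0.00479), blood (0.0105) and Wnt (0.0488, with the direction turned to higher). Without NoDox_d4 replicate 1 they were ATF4 (5.33e-05), BMP (0.0183) and paraxial mesoderm (0.0433), without NoDox_d4 replicate 2 FGF (0.00658), blood (0.00658), mesenchymal (0.0166), immediate early (0.0408) and paraxial mesoderm (0.0452), and without NoDox_d4 replicate 3 blood (0.00273), paraxial mesoderm (0.00703) and mesenchymal (0.0121). Without NoDox_d2 replicate 2 it was FGF (0.0157) and without NoDox_d2 replicate 3 ATF4 (0.0329). Fry called BMP and immediate early (both 0.0386).

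With the replicate number as a block over the NoDox libraries, 4180 genes were called, among them all 1926. That block also called paraxial mesoderm (0.00119), ATF4 (0.0147), blood (0.0247), mesenchymal (0.0268) and BMP (0.0384), and the block over all libraries called paraxial mesoderm (0.0482) and mesenchymal (0.0490). In 4204 genes (23.2%) the groups did not overlap, against 10% by chance. The count of 1926 was 3208, 1281 and 1064 without NoDox_d4 replicates 1, 2 and 3, 206 with only the libraries compared, 4534 without both NoDox libraries numbered 1, and 3201 without those numbered 2 and 3.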

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

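The tests of feeder fibroblasts were chosen only after the results they weigh had been seen, while the counts over other splits of the libraries were planned. In D1Dox_d2, fibroblast genes and Y-linked genes stood high together. The lowest Y-linked sum in D1Dox_d2 was 4.19 CPM and the highest elsewhere 1.06, while Col1a2 stood at 647 to 786 CPM there and Col1a1 at 513 to 630. Xist stood at 12.1 to 19.7 CPM in these libraries and at most 2.01 elsewhere. Y-linked genes and Xist high together argue against the induced cells as the only source of these transcripts. Whether feeder fibroblasts were carried into these libraries cannot be told, since the Y-linked counts were part of what prompted the question. For the Col1a2 rise at day 4 feeders are argued against, since Y-linked counts in D3Dox_d4 were 1.76% of those in D1Dox_d2 while the Col1a2 excess was 47.8%. Xist, which female feeders would bring, stood there at most at 0.627 CPM and Postn at 4.94 to 5.97, against at least 12.1 and 67.2 in D1Dox_d2, so that Col1a2 made by the induced cells stays open.

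Every other split of the 6 libraries at day 2, at day 4 and over time without doxycycline gave 0 genes, against the real 5136, 4263 and 1926 (each 1 of 10 splits), which are too few splits for a share under 0.05. Over time, 4 of these splits part all 3 same-numbered pairs, and those other than the real one also gave 0. For the difference of the effects the real split gave 2336 genes. Only 1 of 100 splits within the days, the real one, reached that, and the highest other gave 1347. That highest other split kept the real groups of day 2 and exchanged libraries only at day 4. These splits exchange doxycycline labels within a day, which widens the spread within groups that differ, whatever made them differ. The share therefore does not exclude an equal effect on both days, or a difference between groups from a source other than doxycycline.

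Lists whose effect differed between the days by a test of the difference, with higher values at day 4, were posterior Hox and Cdx (adjusted p = 0.000228), ATF4 stress response (0.00186), nascent and paraxial mesoderm (0.00459), neural ectoderm (0.0191), glycolysis and hypoxia (0.0297) and primed epiblast (0.0457). Lower at day 4 were fibroblast feeder (1.41e-07), blood and endothelium (0.00153), node and notochord (0.00367), proliferation (0.00367), Nodal pathway (0.0191), lateral plate and cardiac mesoderm (0.0353) and core pluripotency (0.0374). With an estimated correlation 0 of the 27 lists passed in camera for the difference (2 at an unadjusted p under 0.05), and fry called 7. The call was lost without NoDox_d2 replicate 1 for paraxial mesoderm (0.0723) and without NoDox_d4 replicate 1 for core pluripotency (0.139), which was also lost without both NoDox libraries numbered 1 (0.0969), with the stricter filter (0.0685) and with the replicate block (0.0552). Glycolysis was lost without D3Dox_d4 replicate 2 (0.102) or NoDox_d4 replicate 3 (0.0570). Primed epiblast was lost without D3Dox_d4 replicate 2 (0.0603), NoDox_d2 replicate 2 (0.0507) or 3 (0.0587), NoDox_d4 replicate 1 (0.171) or both NoDox libraries numbered 1 (0.0911), and with the stricter filter (0.0633), and lateral plate without NoDox_d2 replicate 2 (0.0508) or 3 (0.0845) or NoDox_d4 replicate 1 (0.155).

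Of the named genes, 67 also had an effect that differed between the days by that test, given as the log2 effect at day 4 minus that at day 2. In 25 of them no single library ended the call or moved the value over 1.5-fold. Higher were Thsd7b (5.36), Hoxaas2 (4.47), Dbh (2.62), Cldn3 (2.36), Dll1 (2.09), Hoxa3 (2.07), Pou3f1 (1.99), Hoxb1 (1.75), En1 (1.68), Gbx2 (1.37), Wnt8a (1.08) and Cited2 (0.81). Lower were Cer1 (−6.29), Epha3 (−6.23), Igfbp5 (−3.75), Esam (−3.60), Postn (−3.28), Esrrb (−3.14), Dkk1 (−3.06), Wnt4 (−2.53), Gata3 (−2.41), Egr1 (−1.47), Mki67 (−1.40), Smarcd3 (−0.999) and Ccna2 (−0.75). Without both NoDox libraries numbered 1, Cer1 was −7.16, Epha3 −7.07, Igfbp5 −2.84 and Postn −2.69. For Postn, and for Dcn, Prrx1, Igf1 and Col14a1 below, the day 2 effect was measured in D1Dox_d2 libraries, where Y-linked sums were highest. A source other than the induced cells stays open for these genes.

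In 15 genes a single NoDox library moved the value over 1.5-fold and none ended the call. Without NoDox_d2 replicate 1, Shh (−5.69) was −6.52, Tek (−2.99) −3.59 and Gli1 (−2.88) −3.56. Without NoDox_d4 replicate 1, Dcn (−4.85) was −3.93, Pmaip1 (−4.10) −3.12, Gata6 (−3.32) −2.12, Lefty1 (−3.00) −2.01 and Vip (3.49) 5.404. Either of these libraries moved Igf1 (−6.41; −7.26 without the first and −3.58 without the second), Inhba (−5.09; −5.81 and −4.25), Cd36 (−5.04; −6.93 and −4.41) and Lhx1 (−3.11; −3.99 and −2.51). Cdh12 (3.31) was 2.52 without NoDox_d2 replicate 2. Gal (5.14) was 4.01 and Tlx2 (4.48) 3.60 without NoDox_d2 replicate 1, and 6.11 and 7.19 without NoDox_d4 replicate 2. Vip and Tlx2 had 1 and 2 counts over the NoDox_d4 libraries.

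In 27 genes the call was lost without 1 library or more, with adjusted p in brackets. Without D1Dox_d2 replicate 2 it was lost for Bnip3 (1.43; 0.0525), Bbc3 (1.16; 0.0524), Sox3 (0.91; 0.0637) and Ecel1 (4.58; 0.0507), and without D1Dox_d2 replicate 3 for Ddit4 (2.52; 0.0510), Sox3 (0.0636) and Ecel1 (0.0513), whose value was 5.18 without NoDox_d4 replicate 2. Gjd2 (4.31) was lost without NoDox_d2 replicate 3 (3.72; 0.130) and was 5.83 without NoDox_d4 replicate 3. The call of mt-Nd1 (−0.96) was lost without D3Dox_d4 replicate 3 or NoDox_d2 replicate 3 (0.0506 to 0.0527), and that of Pfkl (0.71) without D1Dox_d2 replicate 3 or NoDox_d2 replicate 2 or 3 (0.0531 to 0.0576). Dnmt3b (0.74) was lost without replicate 3 of either doxycycline group or NoDox_d2 replicate 2 or 3 (0.0502 to 0.0565), Mef2c (−1.35) without D1Dox_d2 replicate 2 or 3, D3Dox_d4 replicate 3 or NoDox_d2 replicate 3 (0.0551 to 0.0601), and Fgfr1 (0.56) without D1Dox_d2 replicate 1 or 2, D3Dox_d4 replicate 3 or NoDox_d2 replicate 2 or 3 (0.0505 to 0.0595). Pax3 (2.47) was lost without D1Dox_d2 replicate 2 or 3, any D3Dox_d4 replicate, or NoDox_d2 replicate 2 or 3 (0.0594 to 0.0808), and Zic1 (3.55) without any D1Dox_d2 replicate, D3Dox_d4 replicate 1 or 3, or NoDox_d2 replicate 2 or 3 (0.0577 to 0.0787).

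Further genes lost the call without most libraries. Those were Ero1l (0.81; any but D3Dox_d4 replicate 1, NoDox_d2 replicate 1 and NoDox_d4 replicates 1 and 2; 0.0529 to 0.0878), Fgf5 (−2.20; any but D3Dox_d4 replicate 2 and replicate 1 of both NoDox groups; 0.0712 to 0.0874), Klf4 (−1.40; any but NoDox_d2 replicate 1 and NoDox_d4 replicates 1 and 2; 0.0544 to 0.0840) and Acta2 (−2.76; any but NoDox_d2 replicate 1 and the NoDox_d4 replicates; 0.0658 to 0.0829), which was −1.38 without NoDox_d4 replicate 1. Exempt besides NoDox_d2 replicate 1 was NoDox_d4 replicate 1 for Pdk1 (1.24; 0.0525 to 0.103) and mt-Nd2 (−0.89; 0.0601 to 0.104), NoDox_d4 replicate 2 for Cdh11 (−1.50; 0.0569 to 0.108) and Hsph1 (−0.64; 0.0703 to 0.113), and NoDox_d4 replicate 3 for Smad7 (−0.98; 0.0741 to 0.113) and Mcm5 (−0.51; 0.0553 to 0.124). Without NoDox_d4 replicate 1 the values of Dmbt1 (−7.15), Slc26a7 (−7.09), Col14a1 (−6.27) and Prrx1 (−4.24) were −3.94, −2.40, −3.09 and −2.26, and without NoDox_d2 replicate 1 they were −9.75, −8.90, −6.95 and −4.89. Dmbt1 was −8.49 without D3Dox_d4 replicate 3 and lost its call without any library but that, NoDox_d2 replicate 1 and NoDox_d4 replicates 2 and 3 (0.0592 to 0.951). Slc26a7 lost it without D1Dox_d2 replicate 3, NoDox_d2 replicate 2 or 3 or NoDox_d4 replicate 1 (0.0510 to 0.907), Col14a1 without D1Dox_d2 replicate 3, D3Dox_d4 replicate 2 or 3 or NoDox_d2 replicate 2 or 3 (0.0504 to 0.0588), and Prrx1 without D1Dox_d2 replicate 2 or 3, any D3Dox_d4 replicate or NoDox_d2 replicate 2 or 3 (0.0525 to 0.0670). Dmbt1 and Slc26a7, with 2 and 1 counts over the NoDox_d2 libraries, were also lost without both NoDox libraries numbered 1 (both at 0.9998). With the replicate block the calls of Dmbt1 (0.0557), Fgf5 (0.0590), Mcm5 (0.0557), Pdk1 (0.0568) and mt-Nd2 (0.0512) were lost, as were those of Cdh11 with robust moderation (0.0524), Mcm5 with no filter (0.0943) and Pdk1 with upper-quartile scaling (0.0512).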

How the results depend on the processing

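All tests here were planned except the fits without both NoDox libraries numbered 1 or without those numbered 2 and 3, and the NoDox replicate block, which were chosen after seeing the data. In fits leaving out 1 library, genes called numbered 3048 to 7438 at day 2, 2756 to 4286 at day 4, 1226 to 5037 for the difference of the effects and 1064 to 3208 over time, with 1098 to 2214 shared by the days; lists called numbered 7 to 12, 1 to 3, 11 to 18 and 13 to 15. The Mixl1 log2 fold change lay at 3.04 to 8.74 at day 2 and 8.02 to 8.36 at day 4. Without both NoDox libraries numbered 1 the counts were 9902, 7168, 6424 and 4534 genes (3813 shared), with 14 lists at day 2 and 5 at day 4; without those numbered 2 and 3 they were 4687, 7445, 4350 and 3201, the lone controls being assumed to vary like other groups. At an adjusted p under 0.01 they were 2464, 2196, 691 and 775 (756 shared), and against a fold change of 1.5 they were 1731, 1159, 674 and 502. With only the libraries compared, 4737 genes were called at day 2, 3299 at day 4 and 206 over time. Each of these fits has fewer residual degrees of freedom. The fit over time takes its spread from the NoDox libraries alone, whose replicates 1 stood apart. The main fit also takes it from the doxycycline libraries. Over time, 4180 genes were called with the NoDox replicate block. Besides the lists it added, that block changed no other call of a list or named gene over time. With only the libraries compared the Mixl1 rise at day 2 was 3.62 (adjusted p = 0.1203), and with robust moderation 3.62 (0.0507). With an estimated correlation camera called 0 lists in each comparison (4, 1, 2 and 6 at an unadjusted p under 0.05), while fry called 14, 2, 7 and 9. Leaving out 1 library, the Wnt list over time lay at adjusted p 0.0488 to 0.980, turning without NoDox_d2 replicate 1 (0.0488), and the primitive streak list for the difference at 0.0332 to 0.972, turning without the same library (0.0332) or without both NoDox libraries numbered 1 (0.0116). With the replicate number as a block in all libraries, 5105, 4312, 2448 and 1841 genes were called (1647 shared) and 8, 1 and 12 lists at day 2, at day 4 and for the difference; of the calls without the block, 92.2%, 92.6%, 91.0% and 86.2% remained. Same-numbered pairs correlated at −0.125 to 0.545, with 5 of 18 over 0.1, and not every library correlated best with its own number: replicate 2 of NoDox_d2 did with replicate 3 of NoDox_d4 (0.416), and replicate 3 with replicate 2 (0.325 against 0.308). Over all settings, list results kept their side of the threshold, and their direction where called, in 1315 cases, 89 gained a call, 74 lost it and 3 turned with a call; genes taken for the text did so in 3736, 5, 264 and 0 cases, while Mixl1 without a call turned for the difference (−0.53) and over time (0.77) without NoDox_d2 replicate 1. Calls lost without some single library numbered 8 of 64 genes taken for the text at day 2, 10 of 60 at day 4, 19 of 53 for the difference and 15 of 52 over time, and 34 of the last were lost with only the libraries compared. DESeq2 gave a fold change but no p, adjusted or not, for 11 named gene results, among them Mixl1 in all 4 comparisons. The others were Meox1 at day 2, Cd36 and Acta2 at day 4, Igf1, Col14a1 and Prrx1 for the difference, and Hoxc10 over time. These results therefore have no test by DESeq2. Depth set a floor of 0.106 to 0.130 CPM for 3 counts in a library. Where no fewer libraries or stricter thresholds explain a change, the cause was not tested.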

Other observations

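The tests of explanations in this part were chosen only after the results were seen, except that of gene length. Under doxycycline at day 2, camera called none of the signalling lists (Nodal, BMP, FGF and Wnt), although genes in them were called. Of 12 Nodal pathway genes, 3 rose, among them the activin subunit gene Inhba (3.34 ± 0.54, or 4.07 without NoDox_d2 replicate 1) and Smad7 (1.03 ± 0.21), 2 fell and 7 did not pass, likewise adjusted over the list alone (list adjusted p = 0.159, or 0.0377 without NoDox_d2 replicate 1). Of 11 BMP pathway genes, 4 rose, among them Bmp2 (1.61 ± 0.16) and Bambi (1.42 ± 0.23), 1 fell, and 6 did not pass, likewise adjusted over the list alone (list adjusted p = 0.0989). Of 13 FGF pathway genes, 6 fell, among them the receptor gene Fgfr1 (−0.72 ± 0.10) and the feedback inhibitor gene Spry2 (−1.31 ± 0.19), 1 rose, and 6 did not pass (7 and 1 adjusted over the list alone; list adjusted p = 0.0522, with a call without NoDox_d2 replicate 2 at 0.0130 or 3 at 0.0394). The single BMP and FGF genes that moved the other way, chosen after their values were seen, were Id2 (−0.84 ± 0.26) and Spry4 (1.38 ± 0.46, or 2.29 without NoDox_d2 replicate 1). Their calls were lost without any D1Dox_d2 replicate or NoDox_d2 replicate 2 or 3 (adjusted p 0.0670 to 0.132 and 0.0880 to 0.143) and with only the libraries compared (0.0793 and 0.0824), and that of Id2 with the replicate block (0.0515). Of 14 Wnt pathway genes, 2 rose, Dkk1 and the receptor gene Lgr5 (1.22 ± 0.29), 2 fell and 10 did not pass, likewise adjusted over the list alone (list adjusted p = 0.396). The immediate early gene Egr1 rose (1.51 ± 0.13), as did Fos (2.32 ± 0.32, or 2.95 without NoDox_d2 replicate 1), in a list of 11 with 3 up and 1 down, likewise adjusted over the list alone (list adjusted p = 0.0522, with a call without NoDox_d2 replicate 1 at 0.00969 or D1Dox_d2 replicate 2 at 0.0367, or with the replicate block at 0.0419). Of 12 p53 response genes, 5 rose, among them Ccng1 (0.85 ± 0.15) and Eda2r (1.01 ± 0.19), 1 fell, Bbc3 (−1.01 ± 0.19), and 6 did not pass (5 and 2 adjusted over the list alone; list adjusted p = 0.159, or 0.0477 without NoDox_d2 replicate 1). Of 15 glycolysis and hypoxia genes, 5 fell, among them Pfkl (−0.60 ± 0.12) and Pdk1 (−1.15 ± 0.26), and 10 did not pass, likewise adjusted over the list alone (list adjusted p = 0.2996). Of 14 proliferation genes, 5 fell, among them Mcm2 (−0.44 ± 0.08), 1 rose, Ccna2 (0.49 ± 0.11), and 8 did not pass (6 and 2 adjusted over the list alone; list adjusted p = 0.232). Of 13 mitochondrially encoded genes, 1 rose, mt-Nd2 (0.63 ± 0.18, lost without D1Dox_d2 or NoDox_d2 replicate 3, D1Dox_d2 replicate 1 or NoDox_d2 replicate 2 at adjusted p 0.0602 to 0.0996), and 12 did not pass, and its call did not hold adjusted over the list alone (list adjusted p = 0.640). Fry also called the BMP (0.00245), FGF (0.00586), p53 (0.0109) and immediate early (0.000986) lists of day 2, and without both NoDox libraries numbered 1 BMP (0.00312), Nodal (0.00530), Wnt (0.0327) and immediate early (0.0119) were called. Median, mean and camera direction differed in sign for the Wnt and glycolysis lists.

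At day 4, of 11 BMP pathway genes, 3 rose, among them Bmp2 (1.18 ± 0.16) and Bmp7 (0.58 ± 0.15, adjusted p = 0.0524 without NoDox_d4 replicate 3), and 8 did not pass, likewise adjusted over the list alone (list adjusted p = 0.385, called in fry at 0.0118 and without both NoDox libraries numbered 1 at 0.00670). Of 13 FGF pathway genes, 3 fell, among them the feedback inhibitor genes Spry1 (−0.99 ± 0.17) and Spred1 (−0.52 ± 0.09), and 10 did not pass (4 fell adjusted over the list alone; list adjusted p = 0.402). Lgr5 rose again (1.99 ± 0.30) in a Wnt list of 14 with 2 up and 1 down, likewise adjusted over the list alone (list adjusted p = 0.916), and Fos again (1.68 ± 0.33) in an immediate early list of 11 with 1 up and 1 down, likewise adjusted over the list alone (list adjusted p = 0.657). Of 15 glycolysis and hypoxia genes, 5 rose, among them Ero1l (0.96 ± 0.16) and Ndrg1 (1.83 ± 0.41), and 10 did not pass (6 rose and 1 fell adjusted over the list alone; list adjusted p = 0.402). Of 12 p53 response genes, 4 rose, among them Trp53inp1 (0.76 ± 0.14), and 8 did not pass (4 and 1 adjusted over the list alone; list adjusted p = 0.651). The mitochondrially encoded gene mt-Nd1 fell (−0.68 ± 0.16) alone of 13, over all genes and over the list alone (list adjusted p = 0.402, or 0.0170 without NoDox_d4 replicate 1). Of 12 Nodal pathway genes 1 rose, Foxh1 (0.38 ± 0.11, lost without D3Dox_d4 replicate 2 or 3 or NoDox_d4 replicate 3 at adjusted p 0.0584 to 0.117), 1 fell and 10 did not pass, and neither call held adjusted over the list alone (list adjusted p = 0.584). Foxh1 was also lost with no filter (0.0663) and with only the libraries compared (0.107).

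The library labelled NoDox_d2 replicate 1 held Mixl1 at 91.0 CPM. RNA of a doxycycline library mixed in is argued against, since 80 other genes high in D1Dox_d2 stood at a median share of 0.0231 of its level, against 0.237 for Mixl1. For a transgene induced in a part of the cells, 611 genes raised at least 4-fold at day 4 were examined. Their median log2 difference from replicates 2 and 3 was −0.0153 (quartiles −0.451 and 0.394). That cannot decide the question, since whether these genes rise at day 2 was not checked. The effects of the days correlated at 0.400 (Pearson across all tested genes). Brief induction also stays open. Endogenous Mixl1 remains as a hypothesis: all 14 tested genes of the primitive streak list, which does not hold Mixl1, were higher than in replicates 2 and 3, by a median log2 difference of 1.86, so these embryoid bodies could have been further into streak formation.

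The NoDox libraries numbered 1 differed from those numbered 2 and 3 on both days. At least 2-fold differences in one direction on both days were found in 772 genes, and in opposite directions in 35. Of the 772, 681 (88.2%) differed likewise between D1Dox_d2 and D3Dox_d4, against 75.3% of other genes with one sign on both days. Those other genes could carry the same structure at smaller size, so their share is no measure of chance likeness. The comparison therefore cannot tell whether a structure is shared with the doxycycline groups, such as a batch that the labels do not give. Gene length is argued against, with a Spearman correlation of 0.106 at day 2 and 0.0908 at day 4 over 14647 genes. NoDox_d4 replicate 1 also held the highest H19 (4560 CPM), Hoxd9 (67.5) and Hoxc10 (55.5) of all 12 libraries, and no biological explanation was tested.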
